A study of Mus musculus with 10 samples.

How the data were processed

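RNA of whole mouse placentas was measured on 10 Affymetrix expression arrays in 2 experiments. At embryonic day 11.5 (E11.5), 3 wild-type placentas were set against 3 placentas of embryos lacking both Rb and E2f4. At E13.5, 2 Rb null placentas were set against 2 wild-type placentas. Groups were read from the sample titles and the design text. The source labels of the E11.5 null samples name Rb only, whereas their titles and the design text name both genes, so they are called Rb;E2f4 null here. The labels do not say whether replicates came from separate animals. Xist and Y-linked genes differed between replicates in 3 of the 4 groups, so the replicates of those groups were not all repeats of 1 sample, but for the others the spread that p-values measure may be technical.

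The deposited values are log2 probe set levels, 1 column per array, with a range of 0.34 to 14.72. They were made with GCRMA 2.14.1, per the submitters' processing notes, from biotin-labelled cRNA of 5 ug total RNA, per the labels' protocols. GCRMA corrects background and normalizes arrays to each other, which can hide a change in total RNA and compresses values near the floor. The log base was read from the range of the values. The chip definition and any genome build were not given in the sources used here. Array means were 4.47 to 4.48 at E11.5 and 4.15 to 4.16 at E13.5, which looks like separate normalization of the experiments, so tests stayed within an experiment and any level set across them is limited by this. No pair of arrays held identical values (0 pairs). The number of arrays limits the precision.

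The deposited matrix held 45037 probe sets. A supplied platform annotation gave 34945 of them 1 gene symbol, 932 several and 9160 none, and symbols checked through Entrez numbers against RefSeq (GRCm38) needed 0 changes, with 204 numbers not found there. Probe sets with a log2 value above 4 on at least 2 of the 10 arrays were kept, 18737 in all, which removed 58.4%. The 16845 kept probe sets with 1 symbol covered 9920 genes, each represented by its probe set of highest mean. Probe sets of a gene were called in opposite directions for 0 genes, and at E13.5 35 of 302 genes with any call were called only by another probe set than the representative.

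A linear model with the 4 groups was fitted to all 10 arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend. The fit had 6 residual and 3.912 prior degrees of freedom. Contrasts were null minus wild type at each stage and the difference of these contrasts, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Tests were two-sided unless stated. Errors given with log2 changes are limma standard errors, except those of the erythroid and mesothelial medians, which are standard errors over genes.

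Before the data were examined, 22 gene lists were fixed from textbook knowledge: E2F S-phase targets, G2/M and mitosis, pocket proteins with E2Fs and cell-cycle inhibitors, trophoblast stem cells, labyrinth, spongiotrophoblast, giant cells, prolactin family, endothelium, erythroid, decidua, uterine NK cells, macrophages, mesenchyme, yolk sac, p53 targets, hypoxia, imprinted genes, germline genes, immediate early genes, sex-linked genes and interferon response. In these lists 7 symbols were updated. Lists with at least 5 measured genes, 21 of them, were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over lists. Camera with an estimated correlation and fry were the alternatives.

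The genes named were Rb1 and E2f4, the 10 largest rises and 10 largest falls per comparison among called genes whose groups did not overlap, up to 4 members of smallest p per list, up to 10 genes called the same way in both comparisons, and up to 5 genes of smallest adjusted p in the difference. Other members were named where they passed the test adjusted over the list alone or after their values were seen, as stated there.

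Tested on simulated data with 18737 probe sets, 200 of them changed, the E11.5 contrast recovered 9.5% at 1.5-fold, 58% at 2-fold and 96% at 4-fold, with 4, 14 and 26 false calls. The E13.5 contrast recovered 1%, 34.5% and 90.5%, with 0, 2 and 3 false calls. In 21 simulated lists of 40 genes over 9920 genes for E13.5, camera called the 1 list shifted by 0.5 and 0 others. The simulated noise was independent between genes, so lists whose genes vary together were not covered. In the real data the estimated correlation was 0.29 for E2F targets and 0.40 for G2/M genes.

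Alternatives covered the low-value filter (none, log2 above 6, within the experiment), the variance model, each experiment fitted alone, array weights, quantile normalization, median centring, a 2-fold minimum, the mean of a gene's probe sets, the set test and leaving out each array. The estimated correlation together with wild-type E11.5 replicate 1 left out was added after seeing the data. A number shared by the titles of 1 wild-type and 2 null E11.5 samples, which the labels do not explain, was also fitted as a random block and, added after seeing the data, as a fixed block with a level for each number or with 1 term for the shared number. Plots were drawn with matplotlib 3.10.9.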

Results

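Gene expression was measured in placentas at E11.5 and E13.5, days of mouse gestation when the labyrinth, the exchange layer of the placenta, is growing. The samples were 3 wild-type and 3 Rb;E2f4 null placentas at E11.5, and 2 wild-type and 2 Rb null placentas at E13.5. Rb1 encodes the retinoblastoma protein, which binds E2F transcription factors and restrains entry into S phase. E2f4 encodes an E2F that acts mainly as a repressor together with pocket proteins. The comparisons address what loss of Rb, alone or together with E2f4, does to expression in extra-embryonic tissue. Between 16838 and 17476 probe sets per array exceeded the filter value.

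The targeted genes were examined before all others. Rb1 (probe set 1417850_at) fell 8-fold at E11.5, from a mean log2 level of 9.08 ± 0.28 (SD, n = 3) to 6.08 ± 0.42 (SD, n = 3), with a limma adjusted p of 0.000571. At E13.5 Rb1 fell 4.06-fold, a log2 change of -2.02 ± 0.26 (SE), limma adjusted p = 0.0059. That call was lost without Rb null replicate 2 or 3 (limma adjusted p = 0.0551 and 0.0558) or wild-type replicate 4 (0.0777), with changes of -1.96 to -2.09. Every null array lay below every wild-type array in both experiments. A further Rb1 probe set, 1444400_at, stayed under the filter value on all arrays. E2f4 (1451480_at) had means of 5.36 ± 0.11 in wild type and 3.69 ± 0.70 in Rb;E2f4 null (SD, n = 3 each), a fitted change of -1.67 ± 0.35, of uncertain size because the null mean lies near the floor, that did not pass over all probe sets (limma adjusted p = 0.229) but passed when adjusted over the list alone. At E13.5, where the labels give loss of Rb only, its levels were 2.69 in wild type and 2.90 in Rb null, near the floor (limma adjusted p = 0.938). Where these probes lie relative to the deleted parts of the genes was not given in the sources used here, so they check the labels only in part.

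**Figure D1:**
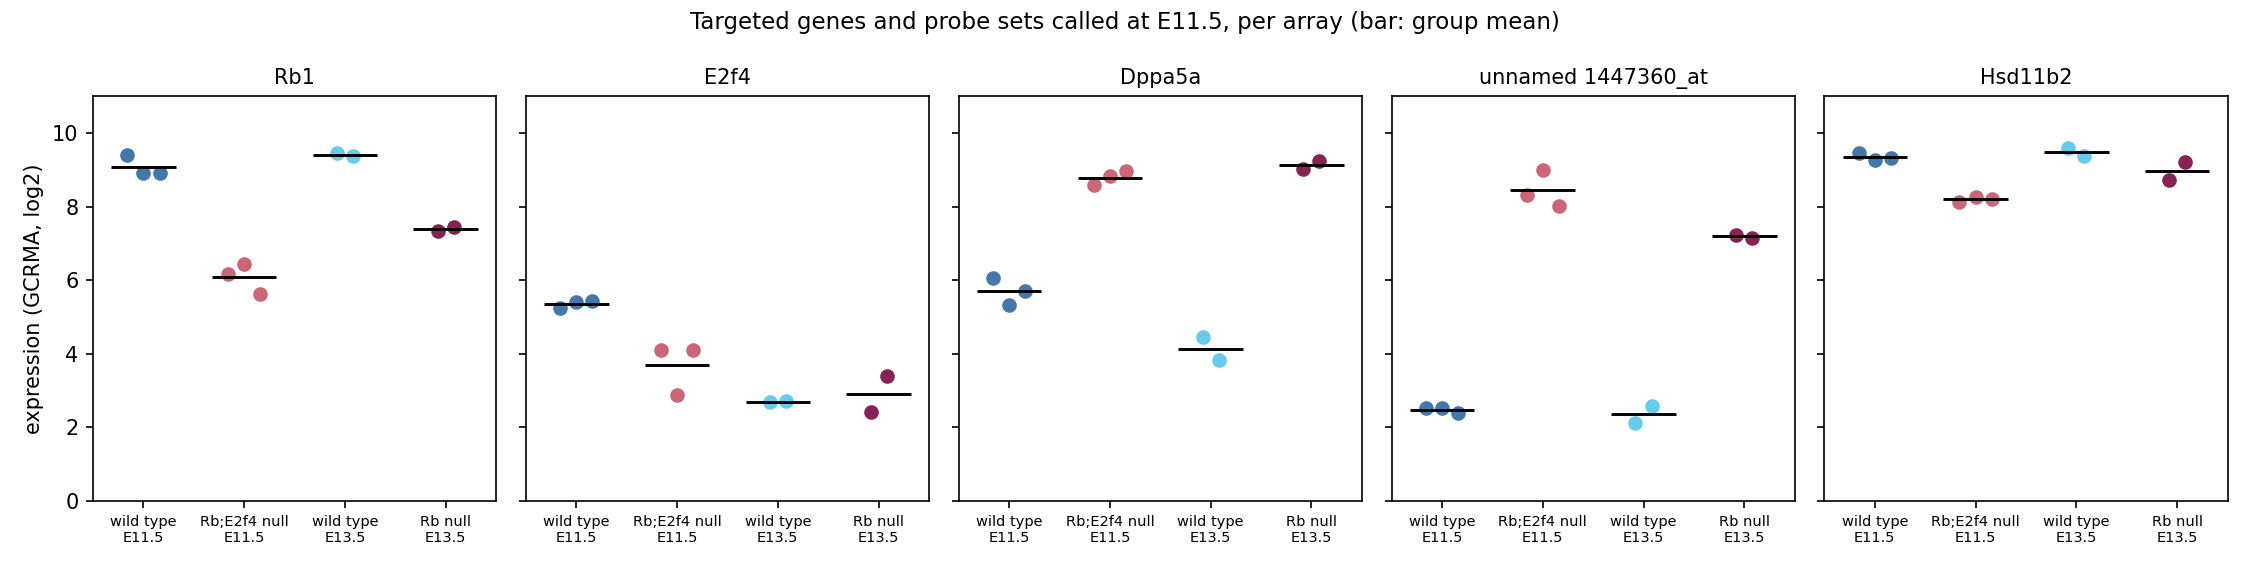
Log2 level on each array (points) by group for the targeted genes Rb1 and E2f4 and the other probe sets called at E11.5, with bars for group means. Rb1 ran from 5.62 to 6.44 in the Rb;E2f4 null arrays and from 8.91 to 9.40 in wild type at E11.5.

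At E11.5 few transcripts separated Rb;E2f4 null from wild-type placentas. Dppa5a, a gene of pluripotent and germ cells, rose 8.57-fold (log2 3.10 ± 0.23, n = 3 per group, limma adjusted p = 0.000571). The unnamed probe set 1447360_at rose from a mean log2 level of 2.47 to 8.44 (limma adjusted p = 7.57e-06). The lower level lies under the filter value, near the floor, so the size of that rise is uncertain. Hsd11b2, the enzyme that inactivates glucocorticoids in the labyrinth, fell by 1.14 ± 0.14 on the log2 scale (limma adjusted p = 0.0375), and it is the 8th nearest measured gene to E2f4 in GRCm38. At E13.5, where the labels give loss of Rb only, its change was -0.515 and was not called (limma adjusted p = 0.181). At E11.5 limma called 4 of 18737 probe sets, 2 higher and 2 lower, Rb1 being the remaining fall. There 1619 had an unadjusted p under 0.05 where 937 would be expected by chance, though in the simulation limma made too many false calls at E11.5. The Hsd11b2 call was lost under 11 of the alternatives fixed before the data were examined, including each E11.5 array left out, with limma adjusted p of 0.0509 to 0.178. With the title number shared by 1 wild-type and 2 null samples as a random block the count was again 4, and within the arrays that share that number the log2 changes were -3.37 for Rb1, 2.84 for Dppa5a and -1.21 for Hsd11b2, against -2.74, 3.07 and -1.16 in the other arrays. As a fixed block with a level for each number, an alternative chosen after seeing the data that rests on those 3 arrays, limma called 0 probe sets, with 1476 at an unadjusted p under 0.05 and 3 residual degrees of freedom, and adjusted p was 0.201 for Rb1 and Dppa5a and 0.465 for Hsd11b2. With 1 fixed term for the shared number it called 7, 2 higher and 5 lower, which included the 4.

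Cell-cycle genes lay higher in Rb;E2f4 null placentas as groups, without a member that passed on its own over all probe sets. For G2/M genes the list medians of the null and wild-type arrays overlapped. Of 60 E2F S-phase targets, which encode DNA replication proteins and their regulators, 55 had positive changes with a median of 0.32. Rpa1 (0.45), Clspn (0.75), Prim1 (0.47) and Blm (0.55) had the smallest p. Limma called 0 of the 60, and 0 when adjusted over the list alone, while 27 had an unadjusted p under 0.05, all higher. The list rose by camera (adjusted p = 9.84e-19), with adjusted p = 0.366 with an estimated correlation. Of 42 G2/M genes 39 were positive, with a median of 0.27, and the list rose by camera (adjusted p = 9.2e-13), with adjusted p = 0.408 with an estimated correlation. Limma called 0 of them over all probe sets, 17 had an unadjusted p under 0.05, and 4 passed adjusted over the list alone, namely Nusap1 (0.51), Pttg1 (0.46), Anln (0.47) and Ndc80 (0.47). By array the E2F median was 0.29, 0.30 and 0.32 in null replicates 1, 2 and 3, and -0.11, 0.19 and -0.07 in wild-type replicates 1, 2 and 3. The G2/M median was 0.273, 0.178 and 0.295 in the null arrays and -0.062, 0.185 and -0.145 in wild type. Wild-type replicate 2 thus lay above null replicate 2 for G2/M genes. Within the arrays that share a title number the medians were 0.42 for E2F targets and 0.30 for G2/M genes, and in the other arrays 0.24 and 0.25.

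Labyrinth genes were lower as a list in the Rb;E2f4 null placentas at E11.5, though not on every null array. Of 27 labyrinth and syncytiotrophoblast genes 23 had negative changes (median -0.35), and the list fell by camera (adjusted p = 1.52e-05), with adjusted p = 0.412 with an estimated correlation. Limma called 1 member, Hsd11b2, and 6 passed adjusted over the list alone. These were Hsd11b2, the transcription factor gene Tfeb (-0.96), the gap junction gene Gjb2 (-0.62), the glucose transporter gene Slc2a3 (-0.89), the transferrin receptor gene Tfrc (-0.50) and Ly6e (-0.70). By array the list median was -0.29, -0.59 and -0.06 in null replicates 1, 2 and 3, and 0.12, -0.04 and -0.06 in wild-type replicates 1, 2 and 3, so null replicate 3 lay at the level of wild-type replicate 3. Without null replicate 2 the list's change was -0.18. Null replicate 2 also had a residual SD of 0.368, where the other E11.5 arrays had 0.238 to 0.276. Within the arrays that share a title number the median was -0.36, and -0.20 in the others.

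The germline list rose by camera at E11.5 (median 0.30, 10 of 13 positive, adjusted p = 0.00327), with adjusted p = 0.408 with an estimated correlation. Limma called Dppa5a alone, and adjusted over the list alone 1 rose and 1 fell, the latter Slc2a3, a glucose transporter gene also held in the labyrinth list. The p53 list rose (median 0.10, 16 of 23 positive, camera adjusted p = 0.0292), with adjusted p = 0.366 with an estimated correlation. Its smallest p belonged to the pro-apoptotic genes Bcl2l11 (1.06), Apaf1 (0.36) and Pmaip1 (0.59) and to Trp53inp1 (0.53). The hypoxia and glycolysis list fell (median -0.20, 17 of 24 negative, camera adjusted p = 0.0292), with adjusted p = 0.893 with an estimated correlation, and its glycolytic members Pgam1 and Hk2 had values of -0.33 and -0.36. Limma called 0 members of the p53 and hypoxia lists, also adjusted over the list alone, with 4 and 3 at an unadjusted p under 0.05. These calls rested on some arrays. Germline was lost without wild-type replicate 2 (0.17, camera adjusted p = 0.0951) or null replicate 2 (0.12, 0.0719), p53 without wild-type replicate 2 (0.08, 0.265) or null replicate 3 (0.08, 0.0558), and hypoxia without wild-type replicate 1 (-0.06, 0.897), null replicate 2 (-0.12, 0.053) or null replicate 3 (-0.21, 0.0558). Within the arrays that share a title number the medians were -0.40 for hypoxia, 0.19 for p53 and 0.15 for germline genes, and in the other arrays 0.02, 0.05 and 0.26, so the hypoxia list was lower within the arrays that share a number but not in the others. With the number as a fixed block with a level for each number, p53 and germline lists lost their calls (camera adjusted p = 0.0822 and 0.15).

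Markers of other cell types did not pass camera at E11.5. List medians were -0.19 for trophoblast stem cells (adjusted p = 0.39), 0.06 for spongiotrophoblast (0.477), 0.06 for giant cells (0.39), 0.13 for the prolactin family (0.16), -0.11 for endothelium (0.267) and -0.16 for erythroid genes (0.39). They were -0.02 for decidua (0.948), -0.54 for uterine NK cells (0.16), -0.20 for macrophages (0.48), -0.02 for mesenchyme (0.977) and -0.30 for yolk sac (0.977). Medians were 0.01 for pocket proteins (0.773), -0.04 for imprinted genes (0.637), -0.06 for immediate early genes (0.977) and 0.02 for interferon response genes (0.903). The mean was negative for pocket proteins (-0.11) and interferon genes (-0.02) although camera placed both lists higher, and camera also placed the yolk sac list higher against its median. Adjusted over the list alone, Rb1 and E2f4 were lower among pocket proteins, 1 trophoblast stem cell gene and 1 immediate early gene were lower, and mesenchyme had 1 higher and 1 lower. Uterine NK genes stood low in wild-type replicate 1, with a list median of -1.46 against 0.80 and 0.68 in the other wild-type arrays. Within the arrays that share a title number, which include it, the NK median was 0.81, and -1.40 in the others. Without that array the NK median was -1.26 (camera adjusted p = 1.08e-09), and spongiotrophoblast (0.30, 0.000423), prolactin (0.24, 0.0326) and macrophage (-0.47, 0.0158) lists passed as well. With that array left out and an estimated correlation, an alternative chosen after seeing the data, none of these passed, with camera adjusted p = 0.33 for NK, 0.533 for spongiotrophoblast, 0.631 for prolactin and 0.533 for macrophage lists. The hormone gene Prl, of the prolactin list, ranged from 2.33 to 10.31 across E11.5 arrays, with 10.31 and 8.42 in null replicates 2 and 3.

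At E13.5 the Rb null placentas differed from wild type at many more probe sets. Limma called 381 of 18737, 280 higher and 101 lower, which stood for 194 genes higher and 73 lower, and 2542 had an unadjusted p under 0.05. Of the called probe sets 160 rose and 65 fell at least 2-fold. The smallest adjusted p, 0.000122, was that of Dppa5a, which rose by a log2 change of 5.00 ± 0.28 (n = 2 per group), with wild-type levels of 4.44 and 3.83 around the filter value. The unnamed probe set 1447360_at, chosen by its E11.5 call, rose from 2.35, near the floor, to 7.19 (limma adjusted p = 0.000203). Leaving out Rb null replicate 2 or 3 lowered the count to 56 or 33, and leaving out wild-type replicate 4 or 5 lowered it to 27 or 156. It was 518 without the Rb;E2f4 null E11.5 replicate 2, 111 with the experiment fitted alone and 681 with array weights.

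The genes with the largest fitted rises at E13.5 were of several kinds. Where a group mean lay under the filter value of 4, near the floor, the size of the change is uncertain, so levels are given in place of folds and the order of such genes is not informative. Hemgn, an erythroid nuclear protein gene, rose from 2.21 to 6.96 (SE of the change 0.52, limma adjusted p = 0.00336), Nptx2, a neuronal pentraxin gene, from 2.29 to 6.30 (0.61, adjusted p = 0.012) and Usp17la, a deubiquitinase gene, from 1.81 to 5.66 (0.71, adjusted p = 0.0253). Ccnb1ip1, which acts in meiotic crossing over, rose from 3.06 to 6.22, Atf7ip2 from 3.42 to 5.90, the nucleoside transporter gene Slc28a3 from 3.67 to 6.10 and the annexin gene Anxa9 from 3.55 to 5.92. With both groups above the filter value, the zinc finger gene Zfp367 rose 5.94-fold and Ung, which removes uracil from DNA, 5.1-fold. Limma adjusted p of these last 6 genes lay between 0.000648 (Zfp367) and 0.0201 (Ccnb1ip1). Dppa5a, Zfp367 and Ung kept their calls with each E13.5 array left out. Nptx2 (limma adjusted p = 0.0505 to 0.125), Ccnb1ip1 (0.0751 to 0.177), Slc28a3 (0.0524 to 0.0685) and Anxa9 (0.0573 to 0.0937) lost theirs with any of these arrays left out. Usp17la lost its call without Rb null replicate 2 or wild-type replicate 4 or 5 (0.106 to 0.204) and with the experiment fitted alone (0.0735), Atf7ip2 without Rb null replicate 3 or wild-type replicate 4 or 5 (0.0505 to 0.0847), and Hemgn without wild-type replicate 4 (0.0503).

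The largest fitted falls at E13.5 are given in the same way. Lrrn4 fell 9.82-fold (log2 -3.29 ± 0.43, limma adjusted p = 0.00628), the potassium channel gene Kcnj13 8.54-fold (-3.10 ± 0.40, 0.0059) and the scaffold gene Pdzk1 6.34-fold, with both groups above the filter value. The transporter gene Slc6a13 fell from 6.84 to 4.00, with the Rb null arrays on either side of the filter value. The Rb null mean lay under the filter value for Rlbp1, a retinaldehyde-binding protein gene, which fell from 6.25 to 2.99 (SE of the change 0.33, limma adjusted p = 0.00229), and for the troponin gene Tnnc1, which fell from 6.39 to 3.49. Likewise Lyve1, a hyaluronan receptor gene of lymphatic and some other endothelium, fell from 5.88 to 3.31, Npl from 6.46 to 3.97, Vtcn1 from 5.24 to 2.81 and Scel from 4.61 to 2.50, Scel with the highest limma adjusted p of the 10 (0.0355). Rlbp1 kept its call with each E13.5 array left out. Scel lost its call with any of them left out (limma adjusted p = 0.0717 to 0.3). Tnnc1 (0.0573 to 0.0752), Npl (0.117 to 0.132) and Vtcn1 (0.0714 to 0.107) lost theirs without Rb null replicate 2 or 3 or wild-type replicate 4. Lrrn4 (0.0551 and 0.0589) and Slc6a13 (0.0736 and 0.107) lost theirs without Rb null replicate 2 or wild-type replicate 4. Kcnj13 (0.0714 and 0.0777) and Pdzk1 (0.0543 and 0.0507) lost theirs without Rb null replicate 3 or wild-type replicate 4, and Lyve1 without Rb null replicate 2 or 3 (0.0551 and 0.0548). With the experiment fitted alone the calls of Tnnc1 (0.0529), Npl (0.0886), Vtcn1 (0.081), Slc6a13 (0.0607) and Scel (0.0543) were lost too.

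Cell-cycle genes rose as groups at E13.5. All 60 measured E2F S-phase targets had positive changes, with a median of 0.99, and 40 were called by limma, 52 when adjusted over the list alone. Examples were the replication genes Prim1 (1.60), Mcm3 (1.29) and Fen1 (1.19) and the chromatin remodeller gene Hells (1.20). The list rose by camera (adjusted p = 6e-50), and with an estimated correlation the adjusted p was 0.0442. All 42 G2/M genes were positive as well, with a median of 0.77, 17 called by limma and 38 adjusted over the list alone. These included the spindle checkpoint target gene Cdc20 (0.61), the kinase gene Nek2 (1.13), the proliferation marker Mki67 (0.94) and Cdca3 (0.86). Without Rb null replicate 2, Rb null replicate 3 or wild-type replicate 4 the calls of Cdc20, Nek2, Cdca3 and Mki67 were lost, with limma adjusted p between 0.0589 and 0.125, and Mki67 lost its call without wild-type replicate 5 as well (0.0737). With the experiment fitted alone Cdc20 (0.0649), Nek2 (0.0674) and Cdca3 (0.0678) lost theirs. Mcm3 lost its call without wild-type replicate 4 (0.0507), and Prim1, Fen1 and Hells kept theirs with each E13.5 array left out. The list rose by camera (adjusted p = 5.43e-31), with adjusted p = 0.106 with an estimated correlation. The E2F list median was 1.02 and 0.94 in the Rb null arrays, and -0.08 and 0.08 in the wild-type arrays.

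**Figure D2:**
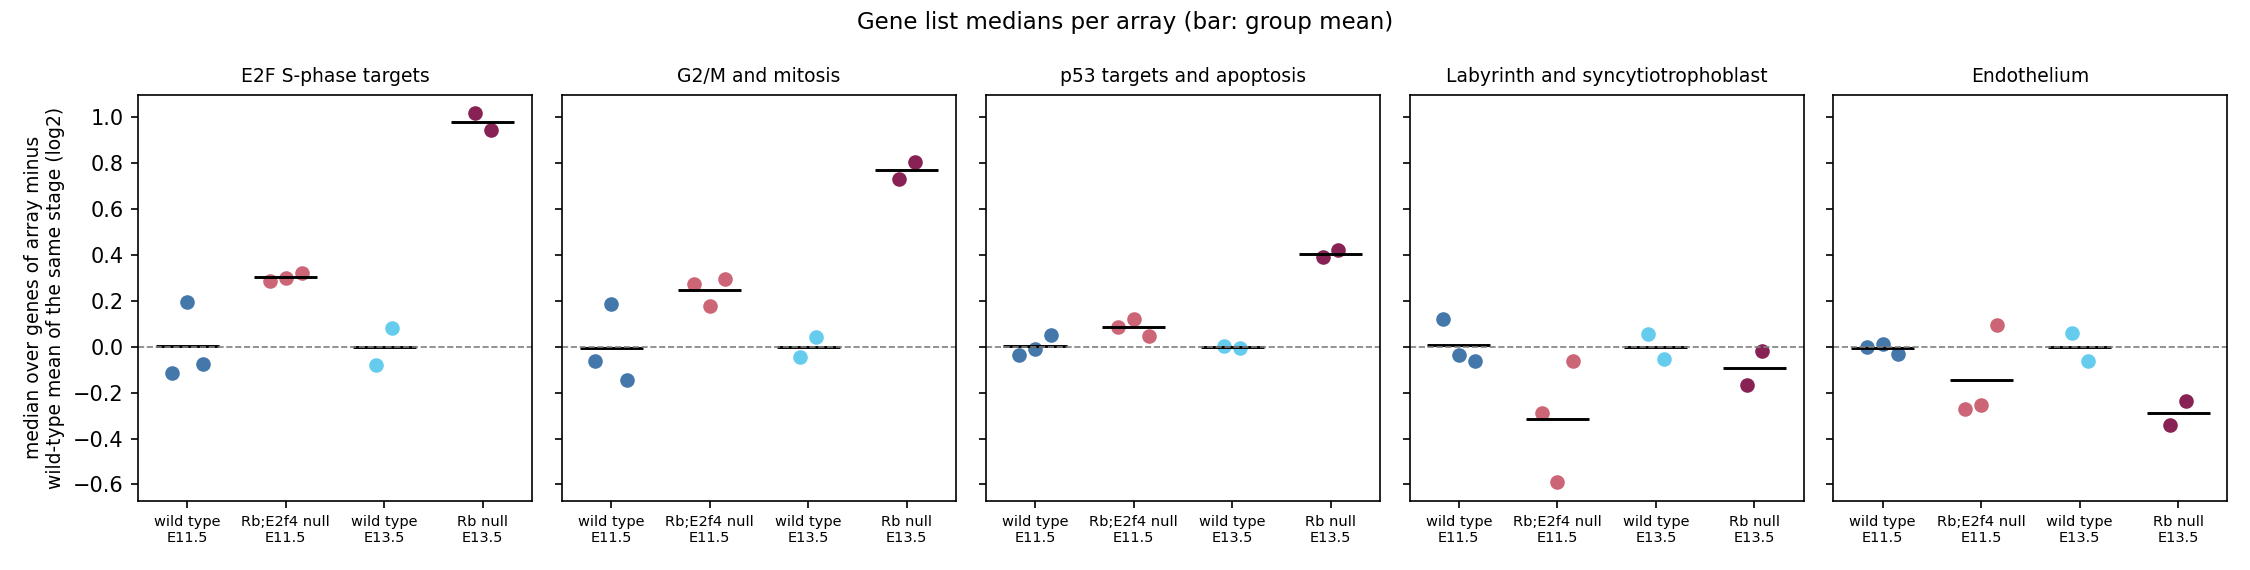
Median log2 difference from the wild-type mean of the same stage (vertical axis) by group, 1 point per array and bars for group means, with a panel each for E2F S-phase, G2/M, p53, labyrinth and endothelial lists. In the E2F S-phase panel the E13.5 Rb null arrays lie at 1.02 and 0.94. The E11.5 null arrays lie between 0.29 and 0.32, and the E11.5 wild-type arrays between -0.11 and 0.19.

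Targets of p53 and apoptosis genes rose at E13.5 as well. Of 23 genes 18 were positive, with a median of 0.41. Limma called Pmaip1 (1.78 ± 0.30, adjusted p = 0.0166) and Bcl2l11 (2.15 ± 0.38, adjusted p = 0.0204), both pro-apoptotic. Bcl2l11 lost its call with each E13.5 array left out (limma adjusted p = 0.0876 to 0.147) and with the experiment fitted alone (0.0566). Pmaip1 lost its call without Rb null replicate 2 or 3 or wild-type replicate 4 (0.107 to 0.163). Adjusted over the list alone 9 rose, among them the CDK inhibitor gene Cdkn1a (1.49), Polk (1.11), Phlda3 (1.11), Aen (0.75) and Ccng1 (0.43). The list rose by camera (adjusted p = 1.42e-05), and the adjusted p was 0.0404 with an estimated correlation. In the list of pocket proteins, E2Fs and cell-cycle inhibitors 23 of 28 were positive (median 0.17). This list shares E2f1, E2f2, E2f3, E2f7, E2f8 and Rbl1 with the E2F S-phase list, so the lists are not independent. Limma called E2f7 (0.81), Lin54 (0.71) and Cdkn2d (0.71) higher and Rb1 lower. Without Rb null replicate 2 or 3 or wild-type replicate 4, E2f7 and Lin54 lost their calls (limma adjusted p = 0.12 to 0.223), and with the experiment fitted alone they had 0.0699 and 0.116. Lin54 had 0.0649 without the filter. Cdkn2d lost its call with each E13.5 array left out (0.109 to 0.248) and under 8 other alternatives. Adjusted over the list alone 4 rose, with Cdkn1a added, and 2 fell, with the cyclin gene Ccnd1 (-0.90) added. The list rose by camera (adjusted p = 0.0141), with adjusted p = 0.288 with an estimated correlation, and lost its call without Rb null replicate 3 (0.17, camera adjusted p = 0.0606) or wild-type replicate 4 (0.07, 0.0613).

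Endothelial genes fell as a list at E13.5 (18 of 25 negative, median -0.30, camera adjusted p = 0.000923), with adjusted p = 0.288 with an estimated correlation. Limma called Lyve1, which lost its call without Rb null replicate 2 or 3 (limma adjusted p = 0.0551 and 0.0548), and adjusted over the list alone 3 fell, including Adgrf5 (-0.43) and the junction gene Esam (-0.58). The giant cell list fell (median -0.10, 10 of 17 negative, camera adjusted p = 0.0419), with adjusted p = 0.288 with an estimated correlation. Limma called 0 of its members, with 4 lower at an unadjusted p under 0.05, and 2 fell adjusted over the list alone, the cathepsin genes Cts6 (-2.22) and Ctsr (-0.33). That list lost its call without Rb null replicate 2 (-0.07, camera adjusted p = 0.0619), Rb null replicate 3 (-0.12, 0.0521) or wild-type replicate 5 (-0.03, 0.301).

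Markers of yolk sac visceral endoderm, among them genes of serum proteins, fell as a list at E13.5 (5 of 6 negative, median -1.43, camera adjusted p = 0.0101), with adjusted p = 0.193 with an estimated correlation. Limma called 0 of them, with 3 lower at an unadjusted p under 0.05, and 2 fell adjusted over the list alone, the alpha-fetoprotein gene Afp (-5.15) and the transthyretin gene Ttr, whose Rb null levels of 3.12 and 2.76 lie near the floor. The wild-type arrays differed strongly here. Afp was 12.9 in wild-type replicate 4 and 8.16 in replicate 5, against 6.58 and 4.17 in Rb null, and Ttr was 10.67 and 5.30 in the wild-type arrays. Without wild-type replicate 4 the list median was -1.01 (camera adjusted p = 0.00923).

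Erythroid genes rose as a list at E13.5 (13 of 17 positive, median 0.19, camera adjusted p = 0.0141), with adjusted p = 0.553 with an estimated correlation. Limma called Hemgn, though not without wild-type replicate 4 (limma adjusted p = 0.0503), and 3 rose adjusted over the list alone, with the blood group genes Rhag (from 2.08 to 4.83) and Rhd (from 2.49 to 3.83) added, both near the floor in wild type. The call was lost without Rb null replicate 3 (-0.01, camera adjusted p = 0.22) or wild-type replicate 5 (0.22, 0.137). The germline list rose by camera (adjusted p = 0.0114), with adjusted p = 0.288 with an estimated correlation, although only 7 of 13 were positive, with a median of 0.07 and a mean of 0.74. Limma called Dppa5a, Tex15 (1.86, adjusted p = 0.0119), which acts in silencing and recombination in male germ cells, and the meiotic cohesin gene Stag3 (1.06, adjusted p = 0.0184). Dppa5a kept its call with each E13.5 array left out. Tex15 lost its call without Rb null replicate 2 or 3 or wild-type replicate 4 (limma adjusted p = 0.088 to 0.125). Stag3 lost its call with each E13.5 array left out (0.0946 to 0.152) and with the experiment fitted alone (0.0537). Adjusted over the list alone 4 rose, with Slc25a31 (from 3.66 to 5.76) added. Without the filter on low values the list median was -0.03 and the camera adjusted p was 0.483.

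Other lists did not pass camera at E13.5. Medians were -0.02 for trophoblast stem cells (adjusted p = 0.845, mean 0.01), -0.14 for labyrinth (0.156), -0.03 for spongiotrophoblast (0.7), -0.07 for the prolactin family (0.45), 0.28 for decidua (0.513) and 0.38 for uterine NK cells (0.645). They were 0.43 for macrophages (0.0738), -0.13 for mesenchyme (0.235), 0.11 for hypoxia (0.11), -0.12 for imprinted genes (0.156), 0.15 for immediate early genes (0.0569) and 0.00 for interferon response (0.747). Among these lists, the tests adjusted over the list alone passed 1 higher gene in trophoblast stem cells, spongiotrophoblast, labyrinth and imprinted genes, 2 lower genes in labyrinth, and 1 lower gene in mesenchyme and in imprinted genes. Only 4 sex-linked genes were measured, too few for the test. The medians were -1.61 at E11.5 and 1.41 at E13.5. This list mixes Xist with Y-linked genes, so its medians follow the sex of the samples. By the Xist levels below, sex was not balanced between null and wild type in either comparison. It was neither in the model nor among the alternatives. Xist, transcribed from the inactive X of females, was between 5.12 and 6.64 on wild-type E11.5 replicates 2 and 3, null E11.5 replicate 2 and Rb null E13.5 replicate 2, and at 10.41 or above on the rest.

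The comparisons were set against each other to ask which changes were common. Dppa5a and 1447360_at rose and Rb1 fell in both, so limma called 3 probe sets in both, 2 higher and 1 lower, where independent calls would share 0.0299 higher and 0.0108 lower. Rb1 was targeted in both experiments, so its fall in both follows from the design, and no other fall was shared. Among the 381 probe sets called at E13.5, 351 had the same sign at E11.5, which was 92.1% against 56.1% of all probe sets tested. The 280 risers had a median of 1.06 at E13.5 and 0.32 at E11.5, and the 101 fallers had -1.19 and -0.39. Examples that did not pass at E11.5 were Lrrn4 (-1.98, limma adjusted p = 0.168), Pdzk1 (-1.10, 0.268), and Rlbp1 and Kcnj13, whose levels of 4.51 and 5.36 in wild type were 2.92 and 3.63 in null, under the filter value (0.14 and 0.169). Across probe sets, which are not independent, log2 changes correlated at Pearson r = 0.247 and Spearman rho = 0.208, with a covariance of 0.0305.

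The difference between the comparisons was tested directly. Limma called 0 probe sets, with 1381 at an unadjusted p under 0.05. The smallest adjusted p was 0.0826 for Ung, followed by 0.0828 for Zfp367, Hemgn and Lrr1 and 0.102 for Flt3, so none of the changes described for E13.5 was shown to differ from E11.5 gene by gene. At E13.5 the change of Lrr1 was 2.33, and the level of Flt3 was 5.62 in wild type and 3.56 in Rb null. Genotype, stage and experiment all differ between the comparisons and cannot be told apart. The count was 11 with array weights, 1 without Rb null replicate 2 and 6 without wild-type replicate 5.

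**Figure D3:**
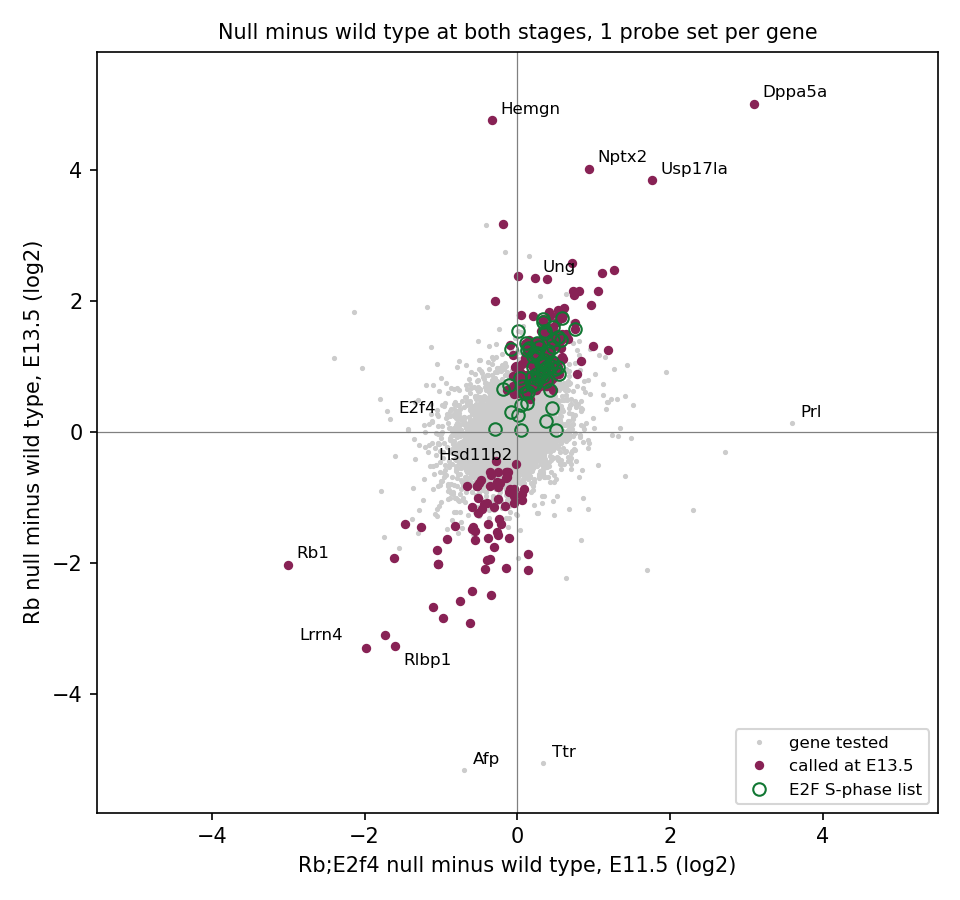
Log2 change at E13.5 (Rb null minus wild type, vertical axis) against that at E11.5 (Rb;E2f4 null minus wild type, horizontal axis) for 9920 genes, with genes called at E13.5 and E2F S-phase targets marked. Dppa5a lies at 3.10 and 5.00 and Rb1 at -3.00 and -2.02.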

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

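The tests of stage in Rb;E2f4 null replicate 2, of yolk sac tissue in wild-type replicate 4 and of the 10 largest falls were chosen only after the result was seen, as was the check on the 500 genes that changed most with stage.

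The change of 12 gene lists differed between the E11.5 and E13.5 comparisons by camera on the difference itself, given here as the E11.5 change minus the E13.5 change. Cell-cycle lists had lower changes at E11.5, by medians of -0.71 for E2F S-phase targets (camera adjusted p = 1.42e-31; adjusted p = 0.128 with an estimated correlation) and -0.48 for G2/M genes (7.38e-16; 0.221 estimated). The same held for p53 targets at -0.31 (0.00442; 0.128 estimated) and pocket proteins at -0.31 (0.00704; 0.221 estimated). Erythroid genes differed by -0.47 (0.00359, estimated 0.461), macrophage genes by -0.49 (0.0315, estimated 0.522), hypoxia genes by -0.32 (0.00398, estimated 0.522) and immediate early genes by -0.28 (0.0464, estimated 0.461). Changes were higher at E11.5 for giant cells by 0.27 (0.00536, estimated 0.221), the prolactin family by 0.24 (0.0455, estimated 0.539), endothelium by 0.14 (0.00985, estimated 0.461) and yolk sac by 0.60 (0.00551, estimated 0.221). None of the 12 passed with an estimated correlation, fry gave adjusted p of 0.018 for E2F and p53 lists, and genotype, stage and experiment are confounded in all of them.

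Across genes, the change in Rb null placentas at E13.5 ran opposite to the wild-type difference between E13.5 and E11.5. Noise of a single wild-type E13.5 array, shared by both sides, is argued against as the whole cause. With different arrays on each side the correlation across genes, which are not independent, was -0.353 and -0.209. A departure common to both wild-type E13.5 arrays would still give a negative correlation and was not tested. Without the 2 cell-cycle lists the correlation was -0.343 and -0.194. Those lists alone thus do not carry it, although cell-cycle genes outside them were kept. The 500 genes highest with stage had medians of -0.29 and -0.13 against wild-type replicates 4 and 5, and the 500 lowest had 0.36 and 0.03. A delay of the Rb null placenta may be a candidate explanation but was not tested apart from the separate normalization, since stage and experiment are confounded.

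Rb;E2f4 null E11.5 replicate 2 stood apart by an array weight of 0.299, while the lowest correlation in its group, 0.9715, is that of replicates 1 and 2 and singles out neither. Its deviation from the other null arrays correlated with the wild-type stage difference at r = 0.411 across genes, which are not independent, against -0.43 for null replicate 1 and -0.148 for replicate 3. These deviations sum to 0 and replicate 1 was as strong the other way, so whether replicate 2 was a more advanced sample cannot be told apart from an earlier replicate 1. The pituitary hormone genes Prl, Gh and Pomc were 10.31, 8.22 and 6.82 there, 8.42, 6.17 and 3.85 in null replicate 3, and 5.73, 3.99 and 5.39 in wild-type replicate 1, the 3 arrays whose titles share a number. Pituitary RNA was left undecided, since Nnat, the 1 other usable marker and also an imprinted gene, differed from the highest other array by -2.24, and no biological explanation beyond stage was tested.

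Yolk sac genes separated the wild-type E13.5 arrays. Over 19 list members replicate 4 exceeded replicate 5 by a median of 3.97, with 18 higher, including Apoa1 (9.88 against 2.90) and Apoa2 (8.98 against 2.96), while replicate 5 exceeded the Rb null mean by a median of 0.22. Yolk sac tissue in replicate 4 may therefore account for part of the list's fall, and how much stays open, since the median of the 6 members kept by the filter was -1.01 without replicate 4, and Lgmn, Sox17 and Slc39a8 are also expressed in the other placentas. For the 10 largest falls, whose median against replicate 5 alone was -2.38, yolk sac tissue was left undecided, since that value rests on 1 array. The genes were chosen as called falls whose groups did not overlap, so each value had to be negative. Lrrn4 (-3.50 against -3.08) and Lyve1 (-2.99 against -2.16) were lower against replicate 5 than against replicate 4, and the rest were lower against replicate 4. Altered cell types in the Rb null placenta stay open as an untested biological difference.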

How the results depend on the processing

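The fixed blocks on the title number, and the estimated correlation without wild-type E11.5 replicate 1 given with its lists, were chosen after seeing the data, and the other alternatives were planned. The E13.5 count of 381 became 111 (87 higher, 24 lower) with each experiment fitted alone, 681 (460 higher) with array weights and 225 (160 higher, 65 lower) with a 2-fold minimum, the last by its construction, and ran from 27 to 518 with arrays left out. The E11.5 count of 4 became 16 (7 higher, 9 lower) with array weights and ran from 3 to 4 with arrays left out. With array weights the difference had 11 calls and both comparisons shared 10, and with arrays left out these ran from 0 to 6 and from 2 to 3. The cause was not tested. An array left alone in its group was assumed to vary like the other groups. With the title number as a random block the E11.5 count was 4 (consensus correlation 0.0352). As a fixed block with a level for each number, which leaves the contrast to the 3 arrays that share one, the count was 0, and the uncalled spongiotrophoblast and uterine NK lists turned to -0.36 and 0.81 with calls at the preset correlation (camera adjusted p = 0.00773 and 0.000407) but not at an estimated one (0.711 and 0.642). With 1 fixed term for the shared number the count was 7, and the lists called at E11.5 with the preset correlation stayed called. No paired analysis was possible because replicate numbers pair no samples: the groups compared at E13.5 share none, and those at E11.5 only name samples. The correlation between comparisons moved to 0.184 without the filter, 0.32 with the mean of probe sets, 0.151 without wild-type E11.5 replicate 1, and 0.143 or 0.299 without Rb null replicate 2 or 3. Lists not called changed sign in 40 of 512 planned tries and genes not called in 11 of 3205. The E2F, G2/M and p53 lists at E13.5 stayed called by camera with the preset correlation with every array left out. With fry no list passed at E11.5, where the smallest adjusted p was 0.131. At E13.5 fry passed E2F and p53 (adjusted p = 0.000667 each), G2/M (0.00412), germline (0.0216) and yolk sac lists (0.0422). Fry did not pass the other lists called by camera at E13.5, namely pocket proteins (adjusted p = 0.0726), endothelium (0.0963), giant cells (0.159) and erythroid genes (0.24).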

Other observations

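The test of erythroid genes was chosen only after the result was seen, the rule for mesothelial markers was tightened to allow for spread after a look at the values, and the comparison with windows across the genome was added then.

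Hemgn, Rhag and Rhd separated the E13.5 groups. Hemgn was 6.05 and 7.88 in the Rb null arrays and 2.18 and 2.25 in wild type, while all E11.5 arrays lay between 7.70 and 8.88. A greater share of red cells is argued against as the whole cause by the values of the 7 erythroid genes abundant in wild type. They changed by a median of 0.055 and by at most 0.56, with a standard error over the genes of 0.0811. That error holds no spread between arrays, so its size does not measure how sure the median is. A change within blood cells, such as their maturity, may remain and was not tested.

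Genes near Rb1 had a small p more often than genes elsewhere. Of the 100 measured genes nearest to Rb1 (order in GRCm38), 18 had an unadjusted p under 0.05 at E11.5 against 9.39% of the 9718 other genes, a one-sided Fisher's exact p of 0.00565, the smallest of 3 such tests. At E13.5 it was 25 of 100 against 15.1% (Fisher's exact p = 0.00703), and near E2f4 at E11.5 it was 12 of 100 (Fisher's exact p = 0.23). Since neighbouring genes are often coexpressed, windows of 100 genes across the genome were counted, and 1.21% of 9897 were as high as that of Rb1 at E11.5, 2.33% at E13.5, and 25.2% for E2f4. Of the 100 genes near Rb1 limma called 8 at E13.5. Lacc1 (1.5), Esco2 (1.535), Diaph3 (1.655) and Pbk (0.79) rose. Sucla2 (-0.44), Slc39a14 (-0.685), Gulo (-1.435) and Shisa2 (-1.4) fell. Strain DNA carried along with the targeted Rb1 allele may be a candidate explanation. Whether the rise of cell-cycle genes at E13.5 adds to the count near Rb1 was not tested. Hsd11b2 is the 8th nearest measured gene to E2f4. At E13.5, where the labels give loss of Rb only, it changed by -0.515 (limma adjusted p = 0.181). Lrch1 is the 7th nearest to Rb1 (-1.24 at E11.5 with limma adjusted p = 0.169, -1.04 at E13.5 with 0.11) and Sucla2 the 5th (-0.44 at E13.5, limma adjusted p = 0.0394). Hsd11b2, Lrch1 and Sucla2 were chosen after their values were seen.

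Lrrn4 and Rlbp1, which fell at E13.5 and had negative values at E11.5, raised the hypothesis of fewer mesothelial cells. The 4 other markers measured, Krt19, Wt1, Ptgis and Msln, had a median change of -0.07 at E13.5. Its standard error over the genes was 0.238, which holds no spread between arrays. No exact test of 2 arrays against 2 can pass the threshold, and limma's fry, a model-based test, gave p = 0.736 for them. Upk3b, Bnc1, Gpm6a, Upk1b, Muc16, Rspo1, Efemp1 and Tmem151a were under the filter value on all arrays, wild type included. Lrrn4 was 8.02 and 8.44 in the wild-type E13.5 arrays, where these markers gave no sign of mesothelial cells. Markers near the floor cannot show a fall, so the hypothesis stays open.

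The 6 E11.5 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4 probe sets and the highest other called 12, so 2 splits gave as many, and that split set wild-type replicates 1 and 2 with null replicate 3 against the rest. Such a count can come from a structure of the samples beyond genotype, which was not tested. For list medians in size, the real value and the highest other were 0.32 and 0.24 for E2F targets (1 split as large), 0.27 and 0.27 for G2/M genes (1 split), 0.35 and 0.37 for labyrinth genes (2 splits), 0.10 and 0.08 for p53 targets (1 split) and 0.20 and 0.22 for hypoxia genes (2 splits). For germline genes they were 0.30 and 0.30 (2 splits), the other being the split that parts the arrays sharing a title number from the rest, with medians of 0.15 within those arrays and 0.26 in the others.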
